A study of Homo sapiens with 6 samples.

How the data were processed

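RNA from HEK293T cells and an alt-LAMA3 knockout derivative was sequenced, with 3 samples per group per the labels. Libraries were made from total RNA with a SMARTer mRNA kit, per the labels' protocols. STAR, Salmon and the genome build hg38 are named per the submitters' processing notes, without version or role. The program that made the table, its model and the direction of its contrast are not given in the sources used here. Per the file headers, the column names are those that DESeq2 gives its results table.

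The table analysed has 6 columns of values. The first is a mean normalized count over all libraries, treated here as a signal, per the file headers the authors' baseMean. The deposited log2 fold change and its standard error are on the log2 scale. The deposited Wald statistic is a score equal to the fold change divided by its error, to within 4.23e-07 over 21091 genes. The deposited p-value equalled the two-sided normal p of that statistic to within 4.99e-08, and the deposited adjusted p equalled Benjamini-Hochberg adjustment over the 13957 genes that have one to within 3.66e-07. The lowest mean of a gene with an adjusted p was 2.2198, and the highest of a gene with a p-value and no adjusted p was 2.2193. Of 33644 genes, 12541 had a mean of 0. The planned minimum of 5 CPM was applied as a mean normalized count of 72.0, which is 5 per 1000000 of the summed means.

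No values per sample were used, since the table holds none. The planned tests on per-sample values, among them fits with other tools, other normalizations, a replicate block and leaving out libraries, were therefore not run, and the deposited comparison was used in their place. The number of libraries was read from means shared by at least 50 genes (tolerance 1e-08) that were not sums of lower such values. That minimum was lowered from 100 after the data had been examined, when a test on simulated data recovered too few libraries, and both minimums gave 9 values in the deposited table. Of 1956 genes with means no higher than the largest such value, 1955 lay at 1 or 2 times one of them. In a wider check, 2127 of 2623 genes (81.1%) under 4 times the lowest value were sums of up to 4 reads over the 9 values, and 1561 (59.5%) over the 6 values of the groups compared, so that 9 libraries did not account for every low gene. Both checks include the genes that defined the 9 values, which had to match. Most of the match was therefore fixed in advance and is no independent evidence for 9 libraries. The geometric mean of the size factors was 1 for 9 libraries. Tested on simulated data, the step search found 9 of 9 and 6 of 6 libraries, over 21103 genes. The minimum had been lowered because such a test missed libraries, and the simulated counts had no differences between groups. This recovery is therefore no independent evidence for the 9 values of the deposited table.

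Gene IDs were matched without version to a table of names (33483 matched) and to GENCODE 29 on GRCh38 (33582 matched, 31959 of them with the same version and 1623 with an older one). The threshold was an adjusted p of 0.05. On simulated data for the deposited comparison with 13957 genes, 99 of 200 genes changed by a log2 fold change of 1 were called, and 143 of 200 at a log2 fold change of 2, with 6 and 7 unchanged genes called. The simulation took the deposited standard errors as exact and changed only 200 genes. Its shares of true and false calls therefore need not hold for the deposited comparison. The exact depth of each library is not known. The size factors times the summed means give approximate totals of 10.9 to 27.3 times 1000000 counts, if normalized totals were equal across libraries. The median standard error was 0.14 for genes with a mean normalized count of at least 72.0 and 0.80 for the 5645 tested genes below that.

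The 33 pathway lists and 8 marker lists were fixed before the data were examined and tested with limma 3.58.1 (R 4.3.3), cameraPR on the deposited statistic with a preset inter-gene correlation of 0.01, two-sided, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment per family. A correlation could not be estimated without values per sample. Of 500 random lists, 2.4% were called by the unadjusted p on simulated data over 13957 genes. Random lists do not carry the inter-gene correlation that real lists may have, for which the test allows. That share therefore does not measure false calls among the lists tested. A further 6 lists were written after the values were seen. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

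Named genes followed a rule fixed before the data were examined. It takes LAMA3, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 72.0, up to 3 members past the threshold with the largest change per list, and the 5 smallest adjusted p-values in each direction. The rule's further condition that groups do not overlap could not be checked. It named 126 genes, not all of which are described, some of them being not reported here, and 5 genes past the threshold known only by an ID or clone name were counted and not named. CD8A, CD3E, CD3D, IL2RA, CORO1A, KRT8, KRT18, NEFL, SALL1, RPL3 and RPL4 were chosen after their values were seen. Alternatives were no filter on low values, a mean of at least 72.0 and a test against a 1.5-fold change. Added after seeing the data were fold changes centred on genes with a mean of at least 72.0, protein-coding genes only, errors widened by the robust spread of all statistics (2.03), and for the lists a correlation of 0.05, ranks and log2 fold changes. Centring was first set on all tested genes, whose median log2 fold change is 0, which changed nothing.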

Results

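The series compared RNA from HEK293T cells with RNA from a knockout line derived from them that lacks alt-LAMA3. HEK293T is a human embryonic kidney cell line that carries the SV40 large T antigen, and alt-LAMA3 is named for the LAMA3 gene, which encodes a laminin alpha chain of basement membranes. The labels give 6 samples in 2 groups, with 3 wild-type and 3 knockout samples, all at day 0, and do not say whether samples of a group came from separate cultures, so that p-values may measure technical spread only. The processed data analysed here are a single table of 33644 genes that holds the result of 1 comparison between 2 groups. It holds no value per sample, and its header names neither group. In what follows, the group whose higher expression gives a positive log2 fold change is called the numerator group and the other the denominator group, and neither is equated with the knockout or the wild type. No statement on the effect of the knockout is therefore made here. Nor can either group be taken to be HEK293T cells, given the levels of marker genes described below.

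The content of the table differed from the labels in 2 measured respects. First, many genes shared exactly the same very low mean, as they do when 1 read in 1 library is divided by the same factor. There were 9 such values, each shared by 149 to 390 genes, where 6 labelled samples would give 6. Genes at 3 of the 9 values had positive log2 fold changes, genes at 3 had negative ones and genes at the remaining 3 had a log2 fold change of 0. Libraries numbering 9, with 3 in each group compared and 3 in neither, would give these values. From the same values, the size factors of the libraries spanned 0.756 to 1.90, a 2.51-fold range, with the highest in the numerator group. The exact total count of each library is not known from the table.

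**Figure D1:**
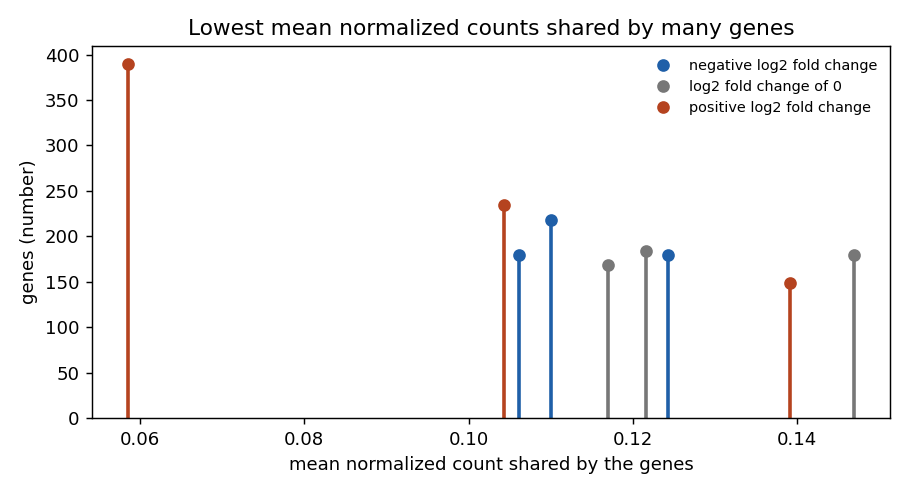
Number of genes (vertical axis) that share each of the lowest mean normalized counts (horizontal axis), coloured by the sign of the log2 fold change of those genes. There are 9 values, 3 for each sign and 3 at a log2 fold change of 0, against 6 labelled samples.

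Second, several genes of blood cells were abundant, and most genes typical of HEK293-derived lines were low, with 2 of 17 at a mean normalized count of at least 72.0. In the authors' deposited table, the mean normalized count was 27074 for CD8A, a co-receptor of cytotoxic T lymphocytes, and 27989 for IL2RA, a subunit of the interleukin-2 receptor. CD3E and CD3D, subunits of the T-cell receptor complex, had mean normalized counts of 13003 and 4959 in the authors' deposited table. By contrast, the authors' deposited table gave 3.42 for KRT8 and 1.45 for KRT18, keratins of simple epithelia, and listed the neurofilament gene NEFL and the transcription factor gene SALL1 at 0. Whether a 0 marks an absent mRNA or uncounted reads is not known, and 1 of 71 genes of the respiratory chain and ATP synthase was also at 0. Among the marker lists fixed before the data were examined, the list of blood cell markers reached a mean normalized count of at least 72.0 in 7 of its 23 members in the table, and CORO1A, an actin-binding protein of leukocytes, reached 21700 in the authors' deposited table. The fibroblast list reached that level in 4 of 18 members, the neuronal list in 3 of 23, the endothelial list in 2 of 14, the keratinocyte list in 2 of 20, the kidney list in 1 of 19, and the adrenal list (15 members) and the stem cell list (16 members) in 0, so that the share of blood cell markers was not far above that of fibroblast markers. The highest mean normalized counts in the authors' deposited table were 1122 in the fibroblast list (ACTA2) and 1396 in the kidney list, against 21700 in the blood cell list.

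**Figure D2:**
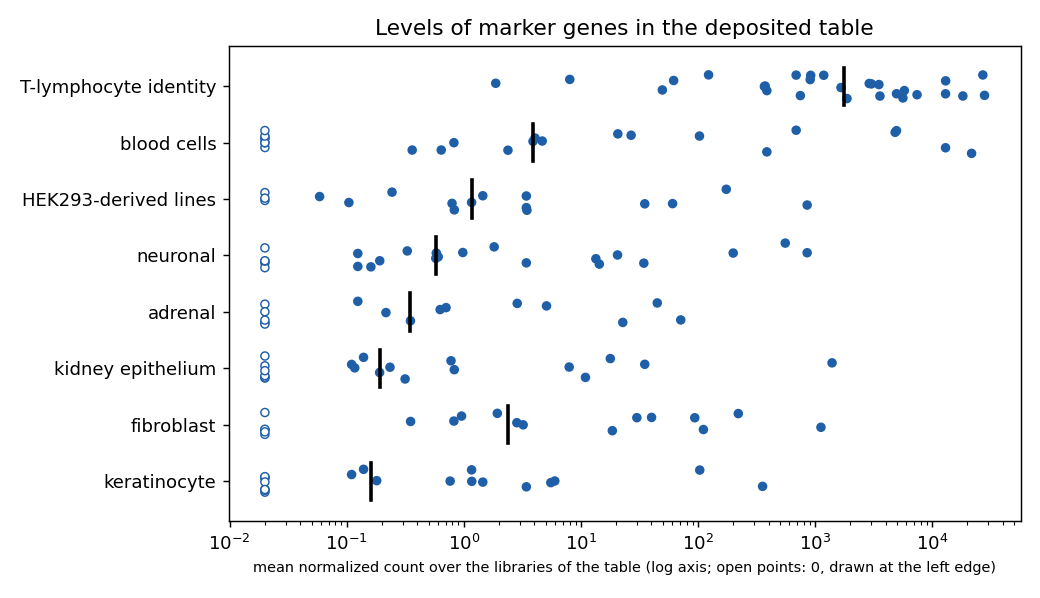
Mean normalized count of each marker gene over the libraries of the table (log axis; 1 point per gene; open points are listed at 0 and drawn at the left edge; black bars are list medians). The median was 1768 for the T-lymphocyte identity list and 1.16 for the list of HEK293-derived lines, both written after the values were seen.

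LAMA3, the locus that names the knockout, lies on chromosome 18 from 23689443 to 23956222 on the plus strand (ENSG00000053747.15; GRCh38, GENCODE 29). Its mean normalized count was 18.98 in the authors' deposited table, with a log2 fold change of -0.62 (SE 0.69, adjusted p = 0.578), so that it did not pass the threshold of 0.05. Levels per sample are not known, and whether the edit would lower this mRNA is not stated in the labels, so LAMA3 gives no check of which group is the knockout.

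The comparison in the table was between groups that differed in many genes. Of 13957 genes with an adjusted p, 4120 (29.5%) passed the threshold, 2054 of them higher and 2066 lower in the numerator group. At least 2-fold changes were seen for 1122 of the 4120, 576 higher and 546 lower. Among genes with a mean of at least 72.0 the count of at least 2-fold changes was 598. Tested as lists, genes of glycolysis, mitosis, the p53 response and the ATF4 response were higher in the numerator group, and interferon-stimulated genes were lower. In each list some members did not pass. The p53 and mitosis lists lost their call with log2 fold changes as the ranking value. The adjusted p-values of single genes are those of the table, which has the column names of a DESeq2 Wald test by the authors. A test of the deposited values against a 1.5-fold change called 653 genes, 569 of them at least 2-fold. With errors widened to the spread of all statistics, an alternative added after seeing the data, 1196 genes were called, 434 of them at least 2-fold. Of the named genes, BCL2L11 (adjusted p = 0.0820), SPP1 (0.212), TPX2, CDC25C, SQLE, MVK, STC2, HYOU1, HSP90B1, TKT, FTH1 and ITGA1 were among those that lost their call against a 1.5-fold change. With widened errors, BCL2L11 (adjusted p = 0.492), SPP1 (0.621), DMBT1 (0.337), GPI (0.184), PFKFB4, STC2, TPX2, CDC25C, SQLE, HYOU1, IFI44L, MX2, AGRN and H3C6 were among those that did.

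The largest rises among genes with a mean of at least 72.0 were led by CDH3, the placental cadherin of cell junctions, at a log2 fold change of 9.09 (SE 1.19, adjusted p = 3.53e-13) in the authors' deposited table. DMBT1 followed at 5.95 (SE 1.53) and ATP12A, a proton pump subunit, at 5.73 (SE 0.16), both from the authors' deposited table. IL23R, a subunit of the interleukin-23 receptor, was at 5.07 (SE 0.17) and PIK3R6, a regulatory subunit of phosphoinositide 3-kinase gamma, at 5.00 (SE 0.18) in the authors' deposited table. PLAC8, DNAJC5B, CDH1 (epithelial cadherin) and the collagen gene COL6A5 were also among the 10 largest rises, with log2 fold changes from 4.16 down to 3.88 in the authors' deposited table.

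The largest falls among genes with a mean of at least 72.0 were of BCL2L11, a pro-apoptotic BCL2 family member, at -4.16 (SE 1.25), and B3GALT2 at -4.14 (SE 0.24) in the authors' deposited table. PTCH1, the Hedgehog receptor, was at -4.03 (SE 0.25) and SPP1 at -3.83 (SE 1.31) in the authors' deposited table. SMAD3, ADGRG2, PLEKHG3, DDX60L and the transcription factor KLF2 were also among the 10 largest falls, from -3.40 to -3.18 in the authors' deposited table. The genes with the smallest adjusted p included CCR4, CCR7, HHLA2, MYH10 and COL6A5 among those higher and CCR2, PICALM, ARHGEF12 and ESYT1 among those lower. Chemokine receptors went both ways in the authors' deposited table, with CCR4 at 1.95 (SE 0.04) and CCR7 at 2.05 (SE 0.06) against CCR2 at -3.16 (SE 0.06).

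Glycolytic enzymes and glucose transporters were higher as a group, with a median log2 fold change of 0.56. Of 25 tested members, 19 were higher, 1 was lower and 5 did not pass, with the same counts adjusted over the list alone (limma cameraPR on the deposited statistics, adjusted p = 4.93e-10). Of the members past the threshold, those with the largest changes are named. The authors' deposited table gave log2 fold changes of 3.30 (SE 0.72) for GPI, 2.38 (SE 0.46) for PFKFB4, a regulator of glycolytic flux, and 2.15 (SE 0.22) for ALDOC, an aldolase. Targets of the hypoxia-inducible factor outside glycolysis had 7 of 15 members higher and 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.000415, cameraPR; adjusted p = 0.478 with log2 fold changes as the ranking value). The median log2 fold change of these targets was 0.34. BNIP3, a mitophagy receptor, was at 1.69 (SE 0.10) and VEGFA, an angiogenic growth factor, at 1.44 (SE 0.12) in the authors' deposited table, while EGLN3, an oxygen-sensing prolyl hydroxylase, was at -1.33 (SE 0.07).

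p53 targets were higher in 15 of 30 tested members and lower in 1 (16 and 2 adjusted over the list alone; adjusted p = 6.80e-10, cameraPR; adjusted p = 0.157 with log2 fold changes as the ranking value). The median log2 fold change of the p53 targets was 0.59. In the authors' deposited table ZMAT3 had a log2 fold change of 1.74 (SE 0.19), PMAIP1, a pro-apoptotic gene, 1.66 (SE 0.09), and CDKN1A, an inhibitor of cyclin-dependent kinases, 1.55 (SE 0.08). Targets of ATF4, a transcription factor of the integrated stress response, were higher in 16 of 28 members and lower in 1, with the same counts adjusted over the list alone (adjusted p = 8.25e-07, cameraPR). Its named members were STC2 at 3.34 (SE 1.26), PSAT1, an enzyme of serine synthesis, at 2.29 (SE 0.25) and VLDLR at 1.98 (SE 0.21) in the authors' deposited table.

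Genes of mitosis were higher in 30 of 40 members and lower in 1, the same adjusted over the list alone (adjusted p = 6.56e-09, cameraPR; adjusted p = 0.0541 with log2 fold changes as the ranking value). The median log2 fold change of the mitosis list was 0.59. The authors' deposited table gave 1.48 (SE 0.37) for the spindle factor TPX2, 1.15 (SE 0.15) for DLGAP5 and 1.06 (SE 0.29) for the phosphatase CDC25C. Genes of DNA replication had 15 of 44 members higher and 1 lower, also the same adjusted over the list alone (adjusted p = 0.0253, cameraPR; adjusted p = 0.207 with a correlation of 0.05 and 0.478 with log2 fold changes as the ranking value), with RFC5 at 1.44 (SE 0.19) and MCM3, a subunit of the replicative helicase, at 1.12 (SE 0.17) in the authors' deposited table. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, were lower in 9 of 35 members and higher in 0 (8 lower adjusted over the list alone; adjusted p = 0.0479, cameraPR; 0.254 with a correlation of 0.05, 0.0636 for protein-coding genes only and 0.0519 without the filter on low values). H3C6 was at -2.00 (SE 0.38) and H2AC6 at -1.81 (SE 0.16) in the authors' deposited table.

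Interferon-stimulated genes were lower in 18 of 31 members and higher in 1 (20 and 1 adjusted over the list alone; adjusted p = 8.25e-07, cameraPR). MX2 at -3.73 (SE 0.78), MX1 at -2.89 (SE 0.46), both antiviral GTPases, and IFI44L at -2.79 (SE 0.70) had the largest falls of the list past the threshold in the authors' deposited table. Endoplasmic reticulum chaperones and unfolded protein response targets were lower in 11 of 26 members and higher in 0, the same adjusted over the list alone (adjusted p = 0.00181, cameraPR; adjusted p = 0.655 with log2 fold changes as the ranking value). The authors' deposited table gave -1.30 (SE 0.37) for HYOU1, -0.97 (SE 0.08) for XBP1, a transcription factor of that response, and -0.84 (SE 0.12) for the chaperone HSP90B1.

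Sterol synthesis genes were higher in 12 of 24 members and lower in 2, the same adjusted over the list alone (adjusted p = 0.0409, cameraPR), and lost the call under 4 of 6 alternatives, with adjusted p-values up to 0.790 for log2 fold changes as the ranking value. SQLE was at 1.26 (SE 0.28) and MVK at 0.74 (SE 0.13) in the authors' deposited table. NRF2 targets and metallothioneins passed with 3 of 15 members higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0479, cameraPR), and lost the call under 5 of 6 alternatives, with adjusted p-values up to 0.627 for log2 fold changes as the ranking value. The 3 that were higher were SLC7A11, a cystine transporter, at 1.09 (SE 0.10), FTH1, the ferritin heavy chain, at 0.67 (SE 0.04) and TKT, a transketolase, at 0.54 (SE 0.04) in the authors' deposited table.

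**Figure D3:**
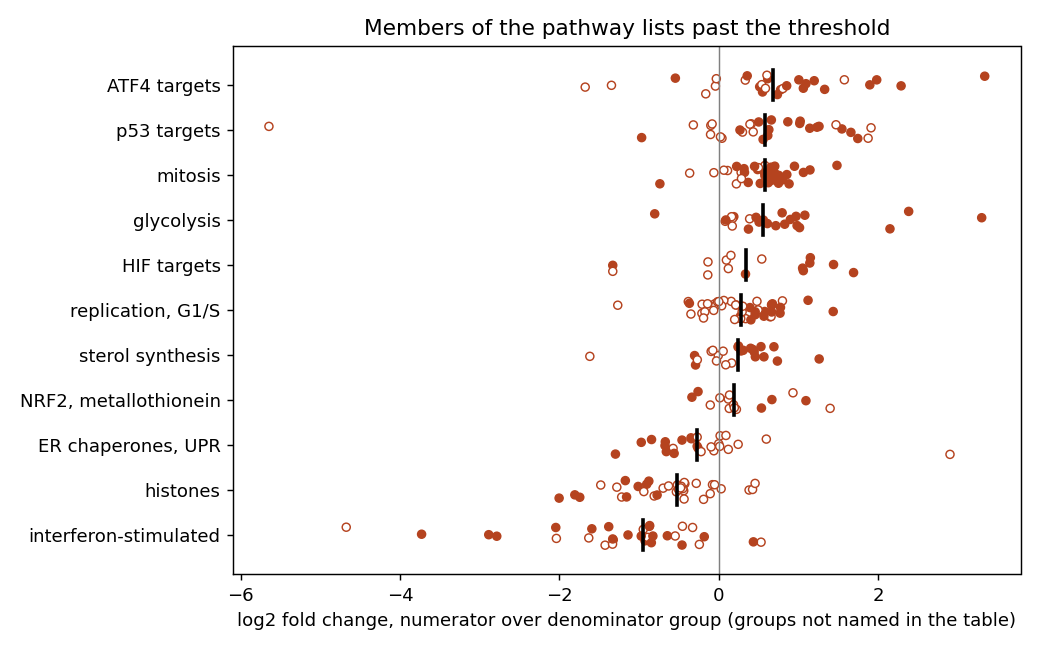
Log2 fold change of each tested member (horizontal axis, numerator over denominator group) of the 11 pathway lists past the threshold; filled points passed the adjusted p of 0.05 over all genes and black bars are list medians. Medians ranged from 0.68 for ATF4 targets to -0.95 for interferon-stimulated genes.

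The other 20 of the 31 pathway lists tested did not pass, although adhesion genes passed with log2 fold changes as the ranking value (adjusted p = 0.00679, with the direction turned from lower to higher) and lysosomal genes with the rank-based test (adjusted p = 0.0197, lower). Laminins, their receptors and basement membrane partners had 2 of 22 tested members higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.942, cameraPR). They included AGRN, a heparan sulfate proteoglycan, at 2.45 (SE 0.59) and ITGA1, an integrin subunit, at -0.93 (SE 0.12) in the authors' deposited table. Proteins of the cytosolic ribosome had 24 of 75 members higher and 9 lower (25 and 9 adjusted over the list alone; adjusted p = 0.172, cameraPR). Of 76 such genes in the table, 25 had a mean normalized count under 497, where the median was 4970, and RPL3 stood at 177 against 45314 for RPL4 in the authors' deposited table. Whether the mean of a single gene counts all of its reads is not known from the table.

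The remaining adjusted p-values from cameraPR were 0.942 for RNA polymerase I and for ribosome biogenesis, 0.216 for the mitochondrial ribosome and for mitochondrially encoded genes, 0.172 for RNA polymerase III and tRNA synthetases, for fatty acid metabolism and for Wnt targets, and 0.372 for the respiratory chain. They were 0.113 for interstitial matrix and for lysosomal genes, 0.614 for adhesion genes, 0.438 for NF-kB targets, 0.265 for immediate early genes, 0.905 for YAP targets and 0.582 for homeobox genes. Heat shock proteins, Notch and TGF-beta targets and imprinted genes each had 0.942. Host genes of small nucleolar RNAs and clustered protocadherins had under 5 tested members and were not tested. Only 1 of the 22 host genes is in the table at all, whereas all 53 protocadherins are, with 4 tested. Most of the 33644 genes are protein-coding (18522) or pseudogenes (14688). For the laminin and the Notch and TGF-beta lists the median log2 fold change was below 0 and the test pointed upward, and for the YAP list the reverse held. None of the 7 marker lists tested passed in cameraPR, the lowest adjusted p being 0.143 (unadjusted p = 0.0204; adjusted p = 0.0220 among genes with a mean of at least 72.0, where it was the only marker list tested) for blood cells, with 2 of 13 tested members higher and 6 lower (2 and 8 adjusted over the list alone). Neuronal, adrenal, kidney, keratinocyte and fibroblast markers had adjusted p-values of 0.781 and endothelial markers 0.806, and stem cell markers had under 5 tested members.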

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

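All tests in this part were chosen only after the result was seen, bounds included.

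The lowest means of the table pointed to 3 libraries outside the comparison, in neither group, as inferred from shared values that did not account for every low gene. Genes of the T-lymphocyte identity list, which was written after the values were seen, had a median mean normalized count of 1768, although the labels name only HEK293T cells and a derivative.

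A candidate explanation for both is that the table belongs to another experiment, but the 9 libraries inferred from the lowest means, against 6 labelled samples, prompted it and lend it no support. T-lymphocyte RNA mixed into HEK293T libraries, and further libraries added to the 6 labelled HEK293T samples, were both argued against by the median of 1.16 for 17 genes typical of HEK293-derived lines, under the bound of 10 and far below the median of 147 of all tested genes, while CD8A and IL2RA ranked 38 and 37 among all genes. Those 17 genes were listed after the values were seen, which weakens the argument. Only 7 of them were tested, whereas the median of 147 leaves out untested genes, which have the lowest means. Gene IDs out of register with their values were argued against by 12 of the 13 mitochondrial protein genes being among the 40 genes of highest mean. Another experiment, by the same authors or others, stays open, since the header names no group, and no biological explanation was tested. The knockout and wild-type labels cannot be assigned to the groups of the table. Given these levels, neither group can be taken to be HEK293T cells, so the changes described above are not results on HEK293T cells.

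Ribosomal protein genes had unequal means, which may bear on other single-gene values. Sharing of reads with processed pseudogenes was argued against as the whole cause, because the 25 low members had a median of only 162 once their named pseudogenes were added (154 without), under the bound of 497. Reads discarded for matching several places stay open, although across the 76 genes, which are not independent replicates, the mean did not fall with the number of pseudogenes (Spearman's rho 0.15, permutation p = 0.193), and rho with the number of annotated transcripts was 0.28, the 2 relations computed. A changed annotation cannot be told apart from other causes, since 7 of 25 low and 11 of 51 other members had an ID version older than GENCODE 29 (odds ratio 1.41, Fisher's exact p = 0.574, two-sided) and the transcripts behind each value are not known. No biological explanation was tested.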

How the results depend on the processing

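The alternatives named as added were chosen after seeing the data. No paired analysis was possible because the table holds no values per library, and for the same reason other tools, normalizations, pseudocounts, leaving out libraries, an estimated correlation, fry and other splits of the samples were not run. The test against a 1.5-fold change called 653 genes, 330 higher and 323 lower, 569 of them at least 2-fold. Errors widened to the spread of all statistics (added) called 1196, 600 higher and 596 lower, 434 at least 2-fold. Among genes with a mean of at least 72.0, at least 2-fold calls were 598 against 1122, and all calls 3797 against 4120. The genes tested were 8312 against 13957, and why at least 2-fold calls fell more was not tested. The test against a 1.5-fold change and the one with widened errors are stricter by construction. Pathway lists past the threshold numbered 11, but 7 with a correlation of 0.05, all among the 11, and 5 with log2 fold changes as the ranking value (both added), 4 of them among the 11; the cause was not tested. The fifth was adhesion genes, whose direction turned (adjusted p = 0.00679). The other counts of genes and lists stayed within 1.5 times. LAMA3 stayed short of the threshold and had no value among genes with a mean of at least 72.0. Glycolysis, ATF4 and interferon lists passed under all 6 alternatives. Of 125 other named genes, 53 lost their call against 1.5-fold, 57 with widened errors and 3 with no filter. Only 103 of the 125 have a mean of at least 72.0, and all 103 kept their call in that setting. The median standard error was 0.80 for tested genes with a mean under 72.0 and 0.14 above; how far depth sets this was not tested.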

Other observations

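All tests in this part were chosen only after the result was seen, on lists written after the values were seen. The adjusted p-values of these lists are therefore no independent evidence of a change.

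Genes of T-lymphocyte identity were lower in the numerator group in 19 of 27 tested members and higher in 1 (adjusted p = 1.10e-12, limma cameraPR, and up to 0.0193 under the 6 alternatives). The authors' deposited table gave log2 fold changes of -0.77 (SE 0.06) for CD3D, -0.51 (SE 0.06) for CD3E and -0.32 (SE 0.07) for CD8A. Cytotoxic effector genes were lower in 8 of 14 members and higher in 0 (adjusted p = 8.43e-06, cameraPR), with the antimicrobial protein GNLY at -2.14 (SE 0.28), PRF1, the pore-forming perforin, at -1.08 (SE 0.07) and NKG7 at -0.89 (SE 0.08) in the authors' deposited table. GZMB, a granule protease, did not pass at -0.05 (SE 0.14) in the authors' deposited table.

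Chemokine receptors and homing molecules were lower in 14 of 19 members and higher in 2, CCR4 and CCR7 (adjusted p = 3.70e-10, cameraPR). CCR2, CCR4, CCR7 and KLF2 were also among the genes named above for the smallest adjusted p or the largest falls. The authors' deposited table gave -3.16 (SE 0.06) for CCR2 and -3.15 (SE 0.34) for CCR3, against 1.95 (SE 0.04) for CCR4. The transcription factor KLF2 was at -3.18 (SE 0.15) and S1PR1, a receptor of lymphocyte egress, at -0.61 (SE 0.04) in the authors' deposited table.

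The list of HEK293-derived lines had 0 of 7 tested members higher and 1 lower (adjusted p = 0.525, cameraPR), and the myeloid list 1 higher and 1 lower of 7 (adjusted p = 0.763). The B-lymphocyte list had under 5 tested members and was not tested.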
